A study of Mus musculus with 4 samples.

How the data were processed

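RNA from lamina propria lymphocytes, the immune cells isolated from the connective tissue under the gut epithelium, was hybridized to 4 one-colour (Cy3) Agilent mouse gene expression arrays. The C57BL6 mice had been given dextran sulfate sodium (DSS), and cells were taken on day 10. DSS is a chemical that injures the colon lining and causes colitis. The 4 groups were wild type with DSS, wild type with DSS and LIF (leukemia inhibitory factor, a cytokine of the interleukin-6 family), Stat4 knockout with DSS, and Stat4 knockout with DSS and LIF. Each group had 1 array and 5 mice were used per group. The labels do not say whether the RNA of the 5 mice was pooled. Mock-treated mice are mentioned in the labels' protocols and are not analysed here.

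The scanner files hold spot intensity values that the authors obtained with Agilent Feature Extraction. The version is 11.0.1.1 per the file headers and 9.1 per the submitters' processing notes. The processed signal used here is the intensity after the background subtraction done by that software, per the file headers. The authors also deposited a table of normalized log2 values of the same arrays. Its columns had medians of 3.31 for wild type with DSS, 2.54 for wild type with DSS and LIF, 3.31 for knockout with DSS and 3.31 for knockout with DSS and LIF. Their Pearson correlation with the log2 scanner values was between 0.971 and 0.992, so the scale is log2 and higher values are brighter. How those values were normalized and floored is not given in the sources used here, and the lowest value of the second column equals its median. That table was used as an alternative.

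Each array had 43020 spots of 39429 non-control probes. Spots marked as non-uniform or population outliers by the software were left out, and log2 values of the remaining spots of a probe were averaged. The main values were log2 processed signals minus the 75th percentile of each array. A probe counted as well above background when at least 50% of its spots carried that mark. No non-control probe was saturated. Probes were named through their RefSeq accessions, without versions, with a RefSeq gene table of assembly GRCm38.p6 that was used for names alone. This matched 27234 of 39429 probes (69.1%) to 20659 genes, and the other probes stayed unnamed. Of these genes 5476 had several probes, and the probe with the highest mean log2 value over the 4 arrays was taken. A gene was measured in a comparison when that probe was well above background on both arrays. A gene whose probes were all below that mark on 1 array received a bound, which is the bright value minus the higher of the dim probe's own value and the dimmest value well above background on that array. Bounds were uneven in direction. For LIF in wild type 253 genes were bounded higher and 1451 lower, and for knockout against wild type under DSS 145 higher and 1033 lower. Medians that include bounded genes carry this imbalance and were not ranked against random lists.

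With 1 array per group no difference has a replicate check and no p-value was computed for a comparison of 2 arrays. Genes were counted by size, at a log2 difference of at least 1. The median SD of the log2 difference over replicate spots of one probe was between 0.099 and 0.103, which covers error within arrays alone. For 30 gene lists the median log2 difference was set among 10000 random lists of the same size, matched on mean log2 expression in 20 bins. These percentiles describe the arrays and are not tests of the conditions. Stat4 itself was left out of the Th1 list between genotypes. As a secondary result limma's lmFit and eBayes fitted genotype and LIF as additive terms on all 4 arrays, with 1 residual degree of freedom, Benjamini-Hochberg adjustment and a threshold of 0.05. That fit uses the interaction as its error.

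Genes named in the text were the 10 highest and the 10 lowest of LIF in wild type, LIF in knockout and knockout against wild type under DSS, and 5 and 5 for knockout against wild type under DSS and LIF and for the difference of the LIF differences. They needed a gene symbol that is not a clone, locus, immunoglobulin or T cell receptor segment name, a difference of at least 2-fold in one direction also with normexp and with quantile scaling, and the same sign in every measured probe. Most of the named genes had only 1 measured probe, so for them the last condition checked nothing. Stat4 and the list members with large differences were named as well, and a summary stands for part of them. The comparisons, the 30 lists, the naming rule and the alternatives named first below were fixed before the data were examined.

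The files hold no mean signal column, so normexp (offset 50) was run on the median signal and the median background. The other alternatives of that kind were quantile scaling, scaling to the median of probes well above background on all 4 arrays, no background filter, probes well above background on all 4 arrays alone, the mean over the probes of a gene, and the authors' table. Normexp with no offset, the 75th percentile over probes well above background on all 4 arrays, genes with a mean log2 value at or above the 75th percentile, and a probe choice without the array of wild type with DSS and LIF were chosen after seeing the data. Scan identity was read from the file headers. Wild type with DSS and knockout with DSS were on scan 1, wild type with DSS and LIF was on scan 2, and knockout with DSS and LIF was on scan 3. A block for the scan could not be fitted with 1 residual degree of freedom.

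The list percentile was tested on simulated data built from knockout against wild type under DSS with 10500 genes. Lists of 12 genes lay above the central 95% of random lists in 1 of 100 simulations with no shift, in 42 of 100 with an added log2 value of 0.5, and in 94 of 100 with 1. The simulated lists held genes drawn independently. Genes of a real list can vary together, so these rates need not hold for real lists. The additive fit was tested on simulated data for genotype over 8045 genes. With noise at the SD of replicate spots it called 50 of 50 genes at each size of change, and 15 unchanged genes. With noise at the residual SD of the real arrays it called 0 of 50 at each size, while its median estimates were 0.95 for a log2 change of 1 and 3.94 for 4. There limma's prior degrees of freedom, the weight of a variance common to all genes, were 1.04, but infinite in the main fit. The SD of replicate spots leaves out differences between arrays. Neither simulation therefore shows how many calls of the main fit are right or missed. The software was R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.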

Results

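Gene expression was measured on 4 arrays of lamina propria lymphocytes taken on day 10 after DSS exposure, 1 array for each combination of genotype (wild type or Stat4 knockout) and treatment (DSS, or DSS and LIF). The arrays differed in brightness. The 75th percentile of the processed signal was 122.9 for wild type with DSS, 23.8 for wild type with DSS and LIF, 45.3 for knockout with DSS and 43.3 for knockout with DSS and LIF. Probes well above background numbered 24339 (61.8%), 14823 (37.6%), 17709 (44.9%) and 18007 (45.8%) of 39429 in the same order. The number of arrays limits the precision of every comparison, because no group has a replicate.

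Stat4, the transcription factor removed in the knockout, was measured by 1 probe that was well above background on all 4 arrays. Its log2 level was −0.49 in wild type with DSS, 0.21 in wild type with DSS and LIF, 0.31 in the knockout with DSS and −0.48 in the knockout with DSS and LIF. The knockout minus wild type difference was 0.80 under DSS and −0.70 under DSS and LIF. The probe therefore did not separate the genotypes. Whether it lies in the deleted part of the gene is not given in the sources used here, and a probe outside that part checks nothing. The arrays of the knockout are called labelled knockout from here on, and every direction between genotypes rests on the labels.

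The array of wild type with DSS and LIF stood apart from the rest. Over 12674 probes well above background on all 4 arrays its Pearson correlation with the others was between 0.800 and 0.818, whereas the other 3 arrays correlated at 0.951 to 0.980 with each other. Probes are not independent replicates in these correlations. In genes with a pair of measured probes, the LIF difference in wild type of the brightest probe and that of the second probe correlated at r = 0.10 over 1286 genes. The same correlation was 0.25 for LIF in the labelled knockout over 1632 genes and 0.39 for labelled knockout against wild type under DSS over 1824 genes.

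**Figure D1:**
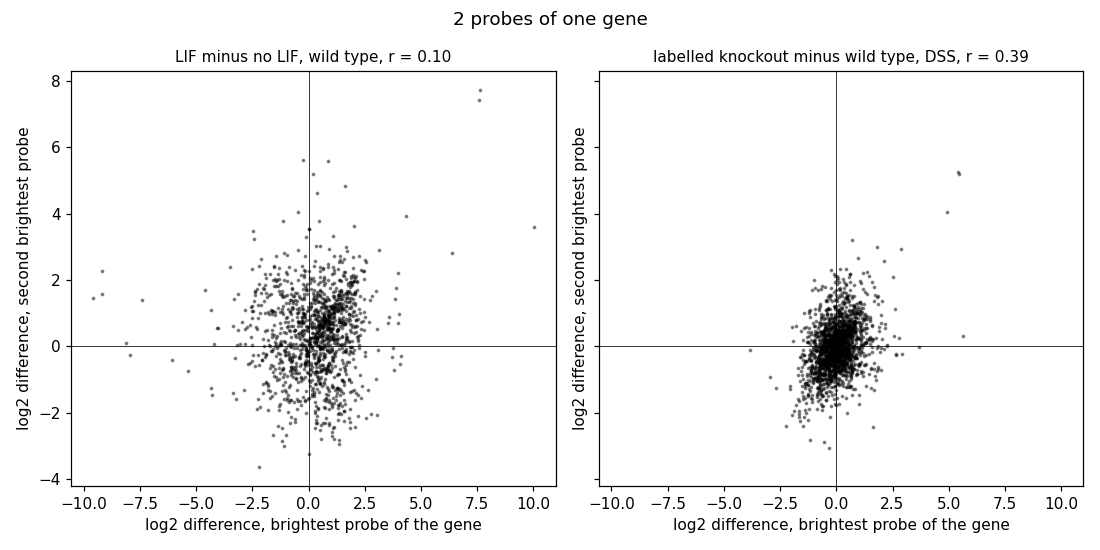
Log2 differences of the brightest probe (x axis) and the second brightest probe (y axis) of a gene, 1 point per gene, for LIF in wild type (left, 1286 genes) and labelled knockout against wild type under DSS (right, 1824 genes). The points on the left form a round cloud with r = 0.10, and those on the right lie closer to a rising line with r = 0.39.

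The comparison of the labelled knockout with wild type under DSS addresses which genes differ with Stat4 in inflamed tissue, and both arrays were read in the same scan. Neutrophil genes were higher in the labelled knockout. Of 14 measured neutrophil markers 10 were at least 2-fold higher and 0 at least 2-fold lower, and the list median was 2.74, above all of the 10000 random lists. It was 2.49 with genes below background on 1 array entered at their bound. The calprotectin subunits S100a8 and S100a9, abundant in neutrophil cytoplasm, were 6.96-fold and 6.37-fold higher, and the antimicrobial peptide gene Camp was 30.5-fold higher. The stefin genes Stfa1 and Stfa2 were 26.5-fold and 30.4-fold higher and the neutrophil collagenase gene Mmp8 was 17.9-fold higher. Among inflammatory cytokines and chemokines 5 of 15 were at least 2-fold higher and 1 lower, with a median of 0.79 (99.84th percentile). The acute-phase gene Saa3 was 16.1-fold higher. Lif itself was 4.27-fold higher, in a LIF receptor and STAT3 pathway list whose median was 0.31 (92.30th percentile).

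NK and cytotoxic genes and interferon-stimulated genes were lower in the labelled knockout under DSS, by their list medians. Of 11 measured NK and cytotoxic genes 5 were at least 2-fold lower and 1 higher, with a median of −0.96, below all of the random lists. Klrd1, which encodes a subunit of an NK cell receptor, was 5.09-fold lower, and the granule genes Nkg7 and Gzma were 2.81-fold and 2.52-fold lower. The chemokine gene Xcl1 was well above background in wild type and not in the labelled knockout, a difference of at least 6.09-fold. Th1 genes split, with 3 of 10 at least 2-fold lower and 1 higher and a median of 0.16 (60.00th percentile), which turned to −0.21 with genes below background on 1 array entered at their bound. Tbx21, which encodes the Th1 transcription factor T-bet, was 2.40-fold lower and Cxcr6 3.67-fold lower, and Ifng, the gene of interferon gamma, was at least 5.63-fold lower. Interferon-stimulated genes had a median of −0.60 (0.57th percentile), with 5 of 12 at least 2-fold lower and 1 higher. The interferon-inducible GTPase genes Iigp1 and Igtp were 5.60-fold and 3.36-fold lower and the transcription factor gene Irf1 2.05-fold lower, while Oas1a was at least 22.1-fold higher. Il21 was 5.47-fold lower in a Th17 list with a median of −0.61 (2.32nd percentile) that turned to 0.26 among bright genes, and Il4 was 4.28-fold lower in a Th2 list with a median of −0.86 (0.39th percentile). Pan-T cell markers had a median of −0.49 (1.08th percentile), with 1 of 14 at least 2-fold lower. Mast cell and eosinophil markers had a median of −0.87 (0.05th percentile), with 2 of 8 lower and 1 higher.

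Markers of further cell types also differed between these arrays. B cell markers were higher in the labelled knockout, with 6 of 12 at least 2-fold higher and a median of 0.96 (99.97th percentile). Stromal and smooth muscle markers had a median of 1.42, above all of the random lists, with 5 of 10 higher, among them the collagen gene Col3a1 (4.41-fold) and the matrix gene Dcn (5.36-fold). Matrix remodelling genes had a median of 1.38 (99.52nd percentile), or −0.088 over the 2 of the 5 genes measured on all 4 arrays, which are too few to rank, and pancreatic acinar markers one of 0.98 (99.90th percentile), or 0.52 with bounded genes. Intestinal epithelial markers had a median of −0.37 (1.77th percentile), with 3 of 23 higher and 5 lower. Medians of macrophage and monocyte (0.04), dendritic cell (0.04), MHC class II (0.12), plasma cell (−0.05), regulatory T cell (−0.17), stem cell (−0.29), proliferation (−0.22), immediate-early (0.12) and housekeeping (−0.12) lists lay within the central 95% of random lists. So did those of the epithelial antimicrobial (0.55), tissue repair (0.74), erythroid (0.83), endothelial (0.24), glia and neuron (−0.09) and sex-linked (−0.29) lists. With bounded genes the sign turned for the dendritic cell list, to −0.28, and for the glia and neuron list, to 0.66. Of all genes with a bound in this comparison, 145 were higher and 1033 lower.

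Over 10500 measured genes, 1387 were at least 2-fold higher and 715 at least 2-fold lower in the labelled knockout under DSS. The higher genes named by the fixed rule were 8 alpha-defensin genes, which Paneth cells express, the defensin pseudogene Defa-ps1, and Stfa3. Defa29 was 62.6-fold, Stfa3 56.6-fold and Defa3 42.9-fold higher. With normexp (offset 50) the log2 difference of Defa29 was 3.44 in place of 5.97. The defensin genes are near-identical copies, so the level of a single one is uncertain. The lower named genes ran from Gsdmc3, 14.2-fold lower, to Trappc2, 6.34-fold lower, and included Ms4a4b (7.04-fold), a T cell membrane protein gene, and the glucagon gene Gcg (6.59-fold). With normexp (offset 50) the counts were 329 higher and 802 lower, so their balance turned. Normexp without an offset gave 1178 and 667, with the balance kept. Among the 8045 genes measured on all 4 arrays 761 were higher and 570 lower.

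**Figure D2:**
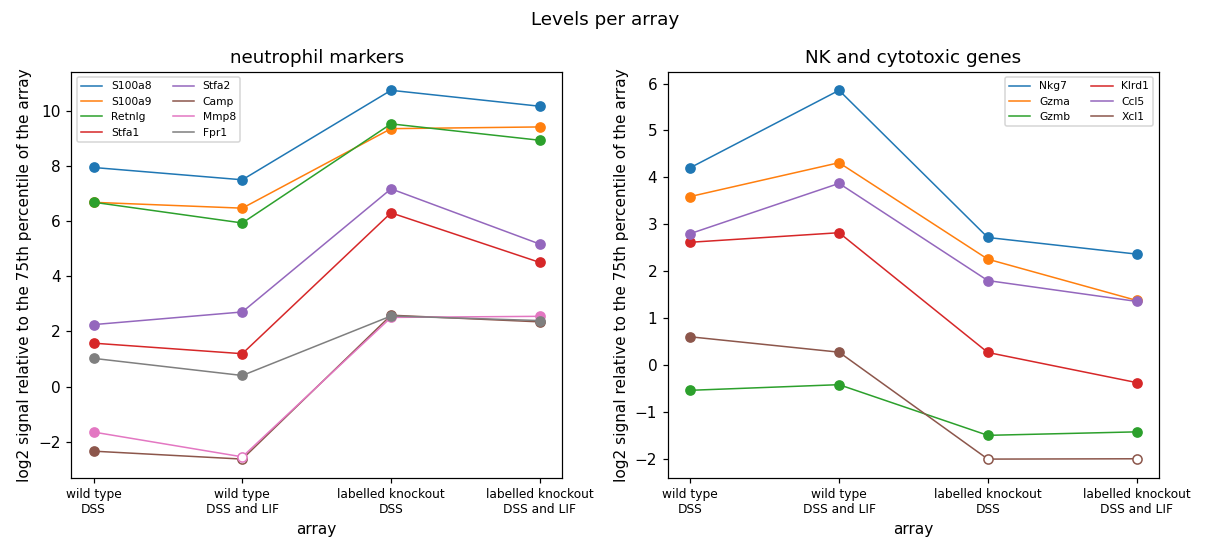
Log2 signal relative to the 75th percentile of each array (y axis) for selected neutrophil markers (left) and selected NK and cytotoxic genes (right) on the 4 arrays (x axis). The other members of these lists are not drawn, among them Klra1 and Fasl, which were higher in the labelled knockout under DSS and LIF. Each line is 1 gene, and open circles are values not well above background. S100a8 lies at 7.95 and 7.50 on the wild type arrays and at 10.75 and 10.17 on the labelled knockout arrays, and Klrd1 lies at 2.62 and 2.82 against 0.27 and −0.37.

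Under DSS and LIF, the comparison of genotypes used the array that stood apart, read in another scan than the labelled knockout array. Neutrophil markers were again higher in the labelled knockout, with 7 of 9 at least 2-fold higher, 0 lower and a median of 2.46 (99.74th percentile). S100a8 was 6.36-fold and S100a9 7.71-fold higher. Pancreatic acinar markers had a median of 2.63 (99.99th percentile) and stromal and smooth muscle markers one of 0.49 (98.72nd percentile). The other ranked lists lay within the central 95% of random lists, and the matrix remodelling, endothelial, glia and neuron, and sex-linked lists had too few measured members to be ranked. B cell markers, higher under DSS, had 0 of 11 higher and 5 lower, with a median of −0.35 (62.14th percentile). Inflammatory cytokines and chemokines had a median of 0.22 (88.45th percentile) and interferon-stimulated genes one of −0.50 (48.44th percentile), or 0.65 and −1.44 with bounded genes. NK and cytotoxic genes had a median of −1.01 (8.96th percentile), or −1.63 with bounded genes. Of 9 measured, 5 were at least 2-fold lower, among them Klrd1 (9.15-fold) and Nkg7 (11.2-fold), and Klra1 (4.12-fold) and Fasl (2.02-fold) were higher. Over 8348 genes 1180 were at least 2-fold higher and 2613 lower, and the median of all measured genes was −0.45, or −0.30 with scaling to the median of probes well above background on all 4 arrays. The counts were 435 and 1203 with normexp (offset 50), 453 and 2843 with normexp without an offset, and 3485 and 4410 with no background filter. The largest named differences were in Olfr15, an odorant receptor gene, 4254-fold higher, and Lrrc19, 78.2-fold lower. Their log2 differences were 12.05 and −6.29, or 8.91 and −3.80 with normexp (offset 50).

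LIF in wild type mice was the treatment comparison of the study, and its arrays were read in separate scans. Over 8963 genes 3093 were at least 2-fold higher and 1216 lower with LIF, and the median of all measured genes was 0.57. That median was 0.43 with scaling to the median of probes well above background on all 4 arrays, so list medians are read against random lists. Matrix remodelling, glia and neuron, and sex-linked genes had fewer than 3 measured members and were not ranked. Of the ranked lists, stromal and smooth muscle markers alone lay outside the central 95%, with a median of −0.32 (1.96th percentile), and that sign turned with normexp (offset 50), to 0.20. MHC class II genes had a median of 1.22 (96.8th percentile), or 1.07 with bounded genes. Of 7 measured, 5 were at least 2-fold higher and Cd74 was 2.10-fold lower, while H2-Aa was at least 3.91-fold lower by its bound. The medians of interferon-stimulated genes (0.99, 68.67th percentile) and intestinal epithelial markers (0.68, 81.88th percentile) lay within the random range. Of 22 epithelial genes 9 were at least 2-fold higher, such as the goblet cell genes Clca1 (log2 difference 4.75) and Tff3 (3.19), and Epcam (6.23-fold), Krt19 (3.17-fold) and Krt8 (2.94-fold) were lower. LIF receptor and STAT3 pathway genes had a median of 0.00 (12.41st percentile), or −0.07 with bounded genes. Of 14 measured, 0 were at least 2-fold higher and 2 were lower, Lif (4.24-fold) and Stat5b (246-fold). Another 5 were lower by their bounds, among them Socs2 (at least 3.84-fold), Lrg1 (at least 2.29-fold) and Pim1 (at least 2.02-fold). Lower bounds prevailed over all genes too, with 1451 lower and 253 higher in this comparison. The higher named genes were 8 alpha-defensin genes, led by Defa29 (1346-fold), with Defa-ps1 and Olfr1466 (439.5-fold). These log2 differences of 10.39 for Defa29 and 8.78 for Olfr1466 became 7.04 and 5.56 with normexp (offset 50). The lower named genes ran from Olfr15 (3078-fold) to Abhd5 (784.5-fold) and included Plvap, Chek1 and Hoxa9. These 10 genes had 1 measured probe each, and log2 levels above 8 on each of the other arrays. With normexp (offset 50) 796 genes were higher and 1525 lower, and with normexp without an offset 2400 and 1303.

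LIF in the labelled knockout gave smaller differences, again between scans. Over 9783 genes 314 were at least 2-fold higher and 301 lower. Pancreatic acinar markers were higher, with 6 of 8 at least 2-fold higher, 1 lower and a median of 1.62, above all of the random lists. The lipase gene Pnlip was 4.79-fold and the trypsinogen gene Prss1 3.88-fold higher. B cell markers had a median of −0.73, below all of the random lists, with 2 of 11 lower, and plasma cell markers one of −0.62 (0.01st percentile). Stromal and smooth muscle (−0.69), erythroid (−0.59), Th1 (−0.37) and dendritic cell (−0.38) medians lay below the central 95% of random lists. Epithelial (0.22), stem cell (0.32) and proliferation (0.29) medians lay above it, and the sign of these last 3 turned with normexp (offset 50), to −0.28, −0.15 and −0.19. All measured genes then had a median of −0.12. Against random lists these 3 stayed on the high side, at the 95.35th, 99.4th and 96th percentiles, with the stem cell list alone outside the central 95%. The dendritic cell median turned to 0.15 (33.16th percentile) with normexp without an offset. The higher named genes were Ncbp3 (8.72-fold), Olfr64 (8.07-fold), Mybl2 (7.64-fold) and Rapsn (4.18-fold), the 4 that met the rule. The lower ones ran from Nudt13 (15.9-fold) to Fam24b (4.27-fold) and included Stfa3 (5.01-fold). The log2 difference of Nudt13 was −3.99, or −1.46 with normexp (offset 50). With normexp (offset 50) 5 genes were higher and 868 lower, and with normexp without an offset 433 and 2364.

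**Figure D3:**
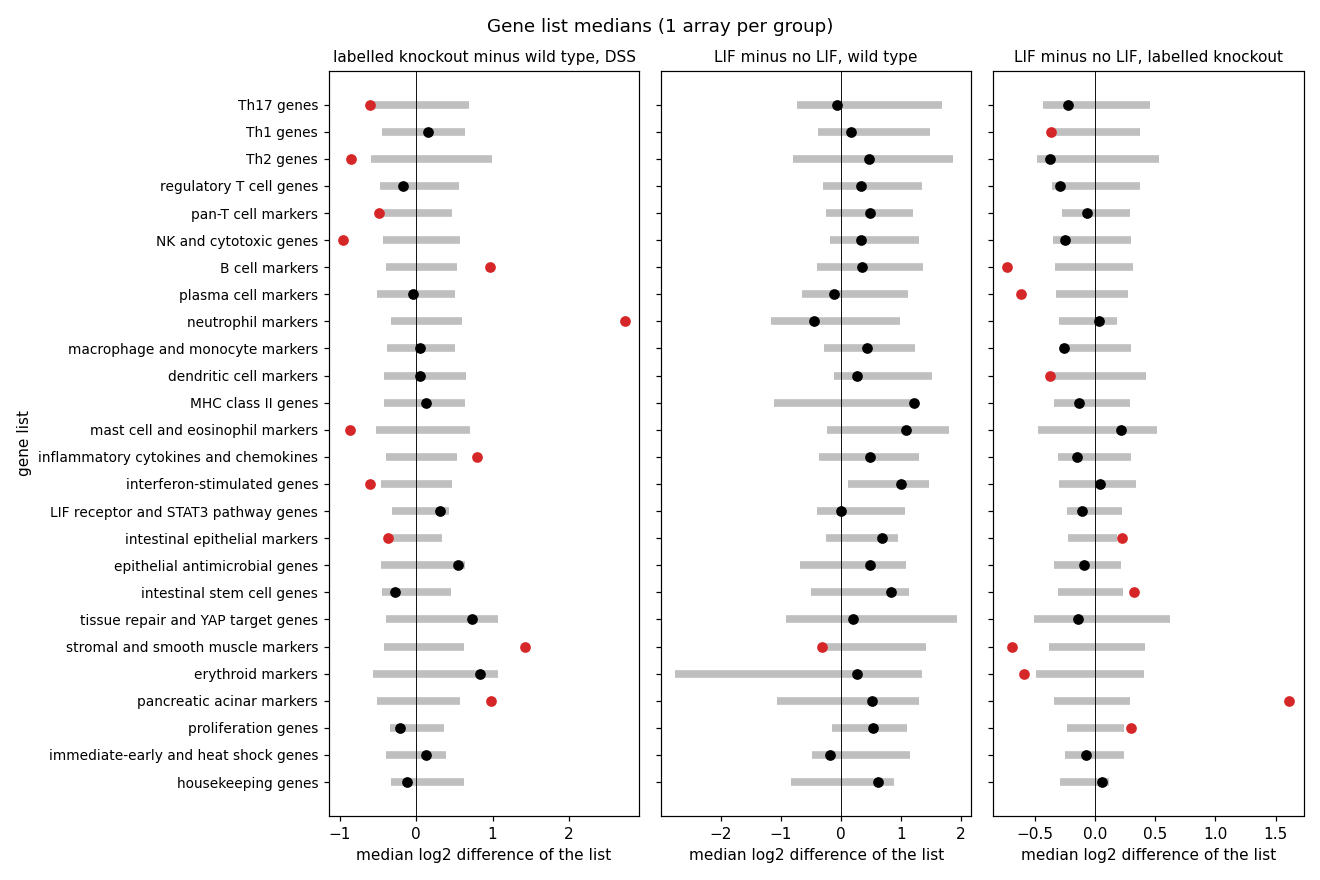
Median log2 difference (x axis, with a different range in each panel) of the gene lists with at least 3 measured members in all 3 comparisons (y axis), for labelled knockout against wild type under DSS (left), LIF in wild type (middle) and LIF in labelled knockout (right). Dots are list medians, in red where outside the central 95% of 10000 random lists, which the grey bars show. Neutrophil markers lie at 2.74 in the left panel, and pancreatic acinar markers at 1.62 in the right panel.

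Whether the LIF difference depended on genotype was asked in 8045 genes measured on all 4 arrays. The LIF log2 difference was at least 1 higher in the labelled knockout than in wild type in 1345 genes and at least 1 lower in 2691 genes. Olfr15 had the highest difference of differences (10.93) and Defa29 the lowest (−10.72). The matrix remodelling, endothelial, glia and neuron, and sex-linked lists had fewer than 3 measured members and were not ranked. No median of the other lists lay outside the central 95% of random lists. Across genes the LIF differences in wild type and labelled knockout correlated at r = −0.07 (Spearman's rho −0.05), with no array in common and with genes that are not independent replicates. With normexp (offset 50) 916 genes had the higher and 741 the lower LIF difference in the labelled knockout, so the balance turned, and r was 0.45. Normexp without an offset gave 721 and 2953, with the balance kept, and an r of 0.35. These differences were not tested.

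In limma's additive fit over 8045 genes, 171 genes were called for genotype (156 higher, 15 lower in the labelled knockout) and 66 for LIF (15 higher, 51 lower) after Benjamini-Hochberg adjustment. Of the 9 neutrophil markers tested for genotype 5 were among the 171, and 5 were called when adjusted over the list alone. Of 8 NK and cytotoxic genes 1 was among the 171, and 3 were called when adjusted over the list alone. With scaling to the median of probes well above background on all 4 arrays limma called 2 genes for genotype and 0 for LIF, with 639 and 234 at an unadjusted p under 0.05. The array that stood apart enters the error of this fit. The fit is valid only where LIF and genotype do not interact, but in 50.2% of these genes the LIF differences differed by at least 1. In the main fit limma's prior degrees of freedom were infinite, so 1 common variance replaced each gene's own residual. A gene that changed in 1 genotype alone can therefore be called, and the calls are not evidence for an effect of genotype or LIF.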

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

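The tests of explanations in this part were chosen after the results were seen. The LIF differences below had opposite signs in the genotypes, each from 1 array per group, and these differences between genotypes were not tested. The labelled knockout minus wild type difference of the median LIF difference was −0.54 for Th1 genes, −1.08 for B cell markers, −0.64 for dendritic cell markers and −0.86 for erythroid markers. With genes below background on 1 array entered at their bound, the erythroid median with LIF in wild type was −0.19, of the same sign as in the labelled knockout (−0.59). The Th1 and dendritic cell medians with LIF in wild type were then 0.03 and 0.03. All measured genes had a median of 0.57 with LIF in wild type, and against random lists the Th1 (16.59th percentile), B cell (28.5th) and dendritic cell (13.82nd) medians lay on the lower side there, as in the labelled knockout. The opposite signs of these 3 lists therefore cannot be separated from the shift of all genes. Over genes measured on all 4 arrays the difference of the LIF differences had a median of −0.53 for all genes, −0.16 for Th1 genes, −1.03 for B cell, −0.18 for dendritic cell and −1.20 for erythroid markers, each list within the central 95% of random lists. Among named genes it was −6.04 for Csprs, −4.42 for Fam24b, −3.45 for Gjd2, −5.31 for Sh3bp4, −5.50 for Tat and −4.88 for Ubap2l. It was 4.47 for Mybl2 and 4.75 for Ncbp3.

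Some control spots that the comparisons do not use were well above background, while most were not. Of 320 E1A spots 33.1% were well above background in wild type with DSS, 10.6% in wild type with DSS and LIF, 14.1% in labelled knockout with DSS and 15.3% in labelled knockout with DSS and LIF. Of 120 ERCC spots the shares were 19.2%, 10.8%, 10.8% and 12.5% in the same order. At most 0.65% of the 153 negative control spots were. The median processed signal of E1A spots was 3.47, 1.85, 2.40 and 3.44 in the same order, and that of negative control spots 2.14, 1.77, 2.19 and 2.31.

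Of 8963 genes 48.1% differed at least 2-fold between wild type with DSS and LIF and wild type with DSS. Among bright genes 47.5% differed at least 2-fold with LIF in wild type and 5.04% with LIF in the labelled knockout. Bright genes were chosen by their mean over the 4 arrays, so they can be dim on wild type with DSS and LIF. With normexp (offset 50) the shares over all measured genes were 25.9% and 8.92%. The low brightness of wild type with DSS and LIF is therefore not excluded as a cause. Signal that belongs to single probes, from labelling or hybridization, is a candidate explanation, because differences of the 2 brightest probes of a gene correlated at 0.10 (95% bootstrap interval 0.03 to 0.18) against 0.39 (0.32 to 0.45) for genotype under DSS. The second probe had the same sign in 58.7% of 617 genes at least 2-fold different by the brightest probe, where second probes permuted among genes gave 54.2% (central 95% from 50.6% to 57.9%). For genotype under DSS it had the same sign in 72.9% of 291 such genes, with no permuted share computed. A LIF effect predicted the same sign in nearly all genes, and no LIF effect a share up to the permuted limit. The value met neither prediction, so it does not decide. A LIF effect in wild type mice stays open, since scan and treatment cannot be told apart with these arrays.

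Neutrophil genes were higher on both labelled knockout arrays. The scan does not account for this under DSS, where both arrays shared 1 scan and the median was 2.74 where the central 95% of random lists ended at 0.60. A lower share of the main cell type would raise other types alike, but the epithelial median was −0.37, the macrophage and monocyte one 0.04 and the stromal one 1.42. The pair of arrays under DSS and LIF gave 2.46 where the random lists ended at 1.22, but this value is part of the pattern and tests no cause of it. More neutrophil RNA in both labelled knockout preparations, whether through genotype, another difference between the mice or the preparations themselves, stays open and untested with 1 array per group.

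Defensin genes were higher on the other 3 arrays than on wild type with DSS, with a median of 5.55 in labelled knockout against wild type under DSS over 11 genes. Paneth cell RNA may contribute, but 6 other Paneth genes had a median of 0.77, above the central 95% of random lists (up to 0.63) and below the value of 1 set for this explanation. These ran from Itln1 (2.89) to Nupr1 (−1.56), with Lyz1, the brightest, at 1.00, and 3 of the 6 (Lyz1, Mmp7 and Ang4) stand in other lists too. The SD over the 11 defensin genes was 0.26 there and 1.13 with LIF in wild type, where Defa29, Defa42 and Defa5 (10.39, 10.01 and 9.32) stood above the other 8 (7.06 to 7.96). That spread argues against 1 signal common to all 11 probes, but it comes from the array that stood apart, so cross-hybridization of near-identical probes stays open.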

How the results depend on the processing

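Of 27 list medians outside the random range, the alternatives gave 234 values that kept their sign and moved by less than about 1 SD of random lists, 47 that moved by more and 12 that reversed. The number of list medians outside that range was between 21 and 28. Of 74 values of named genes they gave 662 that moved by less than a log2 value of 1 and 99 that moved by more. The naming rule itself kept only genes with 1 direction under normexp (offset 50), quantile scaling and all measured probes, so their sign is not tested by these. Normexp (offset 50) alone moved 57 of the 74 named gene values and left 17. Normexp without an offset, the 75th percentile over probes well above background on all 4 arrays, bright genes, and the probe choice without the array of wild type with DSS and LIF were chosen after seeing the data. With that probe choice LIF in the labelled knockout had 319 higher and 303 lower genes, and labelled knockout against wild type under DSS had 1390 and 718. Where a value below changed, the cause was not tested, except that fewer or more genes were counted among bright genes, with no background filter, and among probes well above background on all 4 arrays. Signal over background limits wild type with DSS and LIF most. No paired analysis was possible because each group had 1 array. A scan block and leaving out an array were not run, since the additive fit would keep no residual degree of freedom. The filter on all 4 arrays leaves the additive fit and the difference of the LIF differences the same genes, so it tests nothing there.

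With normexp (offset 50) the labelled knockout minus wild type difference of Stat4 was 0.44 under DSS and −0.18 under DSS and LIF. Genes at least 2-fold higher numbered 796 for LIF in wild type, 5 for LIF in the labelled knockout (868 lower), 329 for labelled knockout against wild type under DSS and 435 under DSS and LIF (1203 lower). The LIF difference was at least 1 higher in the labelled knockout in 916 genes and lower in 741, so the balance turned, and r between the LIF differences was 0.45. The additive fit called 0 genes for LIF and 0 for genotype, with 1356 and 1104 at an unadjusted p under 0.05. The median of stromal markers was 0.20 for LIF in wild type, and with LIF in the labelled knockout those of epithelial (−0.28), stem cell (−0.15) and proliferation genes (−0.19) reversed in sign. All measured genes had a median of −0.12 in the latter comparison. Against random lists the epithelial, stem cell and proliferation medians stayed high, at the 95.35th, 99.4th and 96th percentiles.

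With normexp without an offset Stat4 differed by −0.32 under DSS and LIF, 2364 genes were lower with LIF in the labelled knockout and 453 were higher in it under DSS and LIF (2843 lower). The LIF difference was at least 1 higher in the labelled knockout in 721 genes and lower in 2953, and under DSS 1178 genes were higher and 667 lower in it, so these balances stayed. There r was 0.35 and 128 genes were called for LIF. Medians reversed in sign for stromal markers with LIF in wild type (0.085), and with LIF in the labelled knockout for dendritic cell (0.15), epithelial (−0.65), stem cell (−0.44) and proliferation genes (−0.47). All measured genes had a median of −0.29 in the latter comparison. Against random lists the dendritic cell median lay at the 33.16th percentile. The epithelial (91.9th), stem cell (99.53rd) and proliferation (96.97th) medians stayed on the high side.

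With no background filter the higher and lower genes numbered 8812 and 3334 for LIF in wild type, 2469 and 1163 for LIF in the labelled knockout, 5877 and 2006 between genotypes under DSS, 3485 and 4410 between them under DSS and LIF, and 3978 and 8516 for the difference of the LIF differences. There r was 0.084, 114 genes were called for LIF and the stromal median with LIF in wild type was 0.12. Among probes well above background on all 4 arrays 207 genes were higher with LIF in the labelled knockout, 761 were higher in it under DSS and the matrix remodelling median there was −0.088, over 2 genes alone. Among bright genes 1696 were higher with LIF in wild type, 153 higher and 153 lower with LIF in the labelled knockout, 605 higher and 449 lower between genotypes under DSS, and the Th17 median there was 0.26.

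Stat4 under DSS and LIF differed by −0.55 with scaling to the median and −0.55 with the 75th percentile, both over probes well above background on all 4 arrays. Under these the additive fit called 0 and 0 genes for LIF (234 and 196 at an unadjusted p under 0.05) and 2 and 0 for genotype (639 and 621). With the mean over probes it called 0 for LIF (264 unadjusted) and 3 for genotype. The correlation r was −0.11 with quantile scaling, −0.087 with the mean over probes and −0.11 in the authors' table.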

Other observations

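The tests in this part, and the adipocyte list, were chosen after the data were seen. Adipocyte genes were higher in the labelled knockout than in wild type under DSS, with 7 of 10 at least 2-fold higher and a median of 1.55 (99.94th percentile). The log2 difference was 3.05 for Adipoq, which encodes the fat cell hormone adiponectin, 3.38 for Cfd and 3.75 for Car3. Under DSS and LIF the adipocyte median was −0.06 (89.17th percentile) over 5 measured genes, and 0.29 with 3 more entered at their bound. These were Car3, Cfd and Adipoq, which were below background on wild type with DSS and LIF and higher in the labelled knockout by log2 values of at least 2.71, 1.43 and 0.61. So these arrays do not show that the difference was absent there. With LIF in the labelled knockout the adipocyte median was −0.47 (0.32nd percentile).

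The genotype differences under DSS and under DSS and LIF share no array. Over 8045 genes 278 were at least 2-fold higher in both, where independent lists would share 111.5, and 281 were at least 2-fold lower in both, where independent lists would share 177.6. The correlation across genes was 0.20. With no background filter 787 of 20619 genes were higher in both where 993.3 would be shared, 591 were lower in both where 429.0 would be, and the correlation was 0.042, so the excess of shared higher genes depended on the filter. Among the 8045 genes 164 were higher under DSS and lower under DSS and LIF, and 85 the reverse. With no background filter these numbers were 727 and 451.

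A set of 115 probes was bright on 3 arrays (log2 mean of at least 5) and at least 32-fold dimmer on wild type with DSS and LIF than on wild type with DSS. Their median log2 level was 9.12, −0.03, 10.07 and 9.44 in the order wild type with DSS, wild type with DSS and LIF, labelled knockout with DSS, and labelled knockout with DSS and LIF. The hypothesis that 1 shared labelled species lit these probes predicted a common difference between the labelled knockout arrays. It was not borne out, as the SD of that difference over the probes was 0.76, above the central 95% for probes of like brightness (0.20 to 0.44). These probes thus also varied more than others between the labelled knockout arrays. Probes of this set lay behind 51 of the 66 genes called for LIF and 57 of the 171 called for genotype in limma's additive fit.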
